A study of Homo sapiens with 2 samples.

How the data were processed

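Binding of the transcription factor TCF4 was measured by chromatin immunoprecipitation and sequencing (ChIP-seq) in TMD8, an established line of diffuse large B cell lymphoma of the activated B cell-like (ABC) type. Per the labels, TMD8 has no copy number gain of TCF4 and carried a TCF4 construct switched on by a tetracycline-type drug, and cells received 60 ng/ml doxycycline for 24 hours. The series held 2 libraries, 1 from the TCF4 immunoprecipitate and 1 from the whole cell extract (the input), and both came from induced cells. There was no uninduced library, so binding before induction was not analysed here, and with 1 library of each kind no value had a replicate error.

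BWA, GATK and the hg19 build are named in the submitters' processing notes, with no version or role. The peak caller and its settings are not given in the sources used here. Per the labels' protocols, foreign chromatin with its own antibody was added for normalization, and whether the library scaling used it is not given in those sources. Per the file headers, the authors' table was limited to peaks related to the genes of a signature, each marked Up or Down. How that signature was derived is not given in the sources used here. The table therefore described part of the binding sites, and a gene that it did not name could not be called unbound. It held 662 lines for 661 distinct peaks, because 1 interval was listed under 2 partner regions, and that interval was counted once.

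The authors deposited whole-number counts of ChIP reads and input reads in each peak, per the file headers. The column for the second library carries the letters IC, and it was taken as the input because only 1 other library was named. The authors' deposited log2 ratio equalled log2 of ChIP reads plus 1 over input reads plus 1 in 661 of 661 peaks, within a tolerance of 1e-06. Their normalized log2 ratio was that value plus 0.39 in 661 peaks, which is a library scaling of 1.31-fold. The authors' deposited signal, a normalized read density, equalled reads divided by peak length times 1 constant per library. The unit of that constant is not given in the file headers. If the density is in reads per kilobase and per 1e6 library reads, the constants imply 43.6 M ChIP and 57.0 M input reads (M, 1e6 reads), which were not checked against the libraries. The 1.31-fold scaling is the ratio of these implied totals, each a whole number of reads. Scaling by sequencing depth alone would give that. The totals come from the authors' own normalized values, so they do not decide whether reads had been adjusted by the foreign chromatin beforehand. The authors also deposited a pair of −log10 p-values per peak, of which the local one had a minimum of 2.03 and the one over the whole distribution a minimum of 12.6, with 242 peaks listed as infinite. The −log10 values were not used to rank peaks. The lowest normalized log2 ratio was 1.05 and the lowest ChIP density 2.00, so peaks near these minimums mark the edge of the authors' calling. Every peak overlapped a region of another set that the header did not name, with a median distance between centres of 37 bp and a largest distance of 838 bp. Distances to transcription start sites (TSS) were measured by the authors from that partner region, and position classes and the promoter class were used as deposited.

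From the read counts, a fold of ChIP over input was computed as the ratio of reads times the library scaling, with no pseudocount. Its exact (Clopper-Pearson) interval at the 95% level covers the counting error of independent reads in these 2 libraries only. Reads amplified by PCR are not independent molecules, so the interval is too narrow where such reads were counted. Peaks were ranked by the authors' normalized log2 ratio, called the score hereafter. Shares of peaks have exact binomial 95% intervals.

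Genes were taken as the table named them. Of 275 names, 266 matched a current symbol and 275 matched once older names were used, in a RefSeq gene table of the GRCh38.p14 assembly. That table gave gene lengths and chromosomes only, and no coordinate of it was mixed with the hg19 positions. Before the data were examined, 18 gene lists were fixed from B cell biology, other cell types and general functions. The number of members named by the table was compared with 10000 random lists matched on decile of gene length, drawn from 20077 protein-coding and immunoglobulin constant region genes that included 270 of the named genes, which permutes gene names within length deciles, with a two-sided permutation p and Benjamini-Hochberg adjustment over the 18 lists. Peaks per chromosome were compared with the chromosome's share of protein-coding genes by a two-sided exact binomial test over 23 chromosomes, adjusted in the same way. The planned expectation by chromosome length needed hg19 lengths and was not run. Random placement of peaks and a search for E-box motifs under them also need the hg19 sequence and annotation, which were not used here. Correlations across peaks and across genes had 10000 permutations, whose smallest possible p is 0.0001.

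Genes marked Up and Down were compared in 6 measures by two-sided permutation tests with 100000 resamples and bootstrap intervals of the difference. This comparison was added after the signature column had been seen. Genes named in the text follow a rule fixed before the data were examined: TCF4, the 10 highest-scoring peaks, the 5 genes with the most peaks with ties taken by symbol, and up to 4 members of each list with the strongest peaks, or all members for immunoglobulin genes. A gene that met this rule may not be reported here by name, and stays in the counts. Any other gene is named as chosen after its values were seen. Calculations used Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and figures used matplotlib 3.10.9.

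The procedures were tested on simulated data. Among random lists of 25 genes with no planted member, 1.5% had a p under 0.05, and lists with 4 planted members were found in 100% of draws from the 20077 genes. The fold interval held the true value in 95.8% of 661 peaks simulated with independent reads. For the 275 genes, values were simulated with a spread near that of the score of a gene's strongest peak. Up against Down had a p under 0.05 in 7% of simulations with no difference and in 100% with a log2 difference of 0.5. Measures with another spread, such as peaks per gene and the promoter share, were not simulated. Alternatives covered stricter score limits, merging of near peaks, other TSS windows, other rules for assigning a peak to a gene, and an unmatched Fisher's exact test. Leaving out chromosomes 3 and 18, genes marked Down or narrow peaks was chosen after the data were seen.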

Results

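TCF4 is a basic helix-loop-helix transcription factor of the E protein family, with known roles in B cell and plasmacytoid dendritic cell development. Its binding was mapped after induction in TMD8 cells, and the authors' table listed the peaks at the genes of a TCF4 signature. The question was where induced TCF4 lies at these genes. The 661 peaks held 71988 ChIP reads and 12661 input reads. A peak had a median of 73 ChIP reads, from 15 to 899, and a median of 17 input reads, from 2 to 82. All folds compare 1 ChIP with 1 input library, without replicates.

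The peaks were assigned to 275 genes, of which 229 were marked Up with 545 peaks (82.5% of peaks) and 46 were marked Down with 116 peaks. Median enrichment over input was 6.36-fold, with quartiles of 4.51 and 8.73 and a range of 2.14 to 38.6. The 95% interval of the fold lay above 1 in 660 peaks and above 2 in 565 peaks. The authors called these peaks from the same libraries, with normalized ratios of at least 2.07, so the counts do not test enrichment independently. The exception at 1 was E2F2, a transcription factor of the cell cycle, with 18 ChIP and 11 input reads and a fold of 2.14 (0.958 to 5.02). Peak width had a median of 492 bp, from 150 to 2700 bp.

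The highest-scoring peak lay within HIVEP1, a zinc finger transcription factor gene, at chromosome 6 from 12044501 to 12045280 (hg19), 32200 bp from the TSS. It held 478 ChIP and 21 input reads, a fold of 29.8 (95% interval 19.3 to 48.6). The next was downstream of MBP, the gene of myelin basic protein, at chromosome 18 from 74666276 to 74667001, with a fold of 27.9 (17.6 to 46.9). CRYZ, which encodes a quinone reductase, had a promoter peak of 28.3-fold (16.6 to 52.5). SHQ1 and ZNF267 had folds of 38.6 (10.2 to 326) and 36.01 (9.51 to 305), but each rested on 2 input reads. PITRM1, a mitochondrial peptidase gene, had a fold of 24.7 (15.4 to 42.1), and ALOX5, an arachidonate lipoxygenase gene, had 23.8 (11.2 to 60.3). IFITM1, an interferon-induced membrane protein gene, had a peak of 22.3-fold (13.0 to 41.3) downstream of the gene. That peak lay 109.5 bp from the gene end and 1391.5 bp from the TSS, and so fell in the promoter class. CDKN3, a cell cycle phosphatase gene, had 21.9-fold (12.3 to 43.2) upstream. ZNF580 had a peak of 22.1-fold (13.9 to 37.2) whose apex lay 2 bp from its border. The peaks of PITRM1, ZNF267 and CDKN3 lay 118026, 120538 and 113856 bp from the TSS, and the others of these 10 lay nearer. Each gene name is the authors' assignment. Of these 10 genes, ZNF267 and IFITM1 were marked Down and the other 8 Up. The intervals of the 10 folds overlapped, so their order was within counting error.

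TCF4 itself was marked Up and had 5 peaks on chromosome 18 between 52886051 and 53017282, 4 within the gene and 1 downstream of it. Their folds ran from 3.27 (1.79 to 6.26) to 8.97 (4.98 to 17.5), and none was in the promoter class. The strongest, from 53016826 to 53017282, held 89 ChIP and 13 input reads.

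Many genes carried several peaks. Of the 275 genes, 106 had 1 peak, 169 had 2 or more and 31 had at least 5, with a mean of 2.40 ± 1.74 (SD). FOXP1, a forkhead transcription factor gene, and NEDD4L, a ubiquitin ligase gene, had 10 peaks each. The folds at FOXP1 ran from 2.96 to 8.40, with 7 peaks within the gene and 3 downstream. All 10 peaks of NEDD4L lay within it, with folds from 3.06 to 15.7. BCL2, the gene of the anti-apoptotic protein, had 9 peaks of 5.28 to 9.36-fold, 1 of them in its promoter class with 8.22-fold (5.37 to 13.1). TRAK1, a mitochondrial transport adaptor gene, also had 9, of 4.50 to 12.7-fold. FAM49A, marked Down, had 8 peaks of 3.02 to 10.6-fold, a number shared with PMAIP1 and SYK. Longer genes had more peaks (Spearman's rho 0.36, Pearson's r 0.39 with log10 length, permutation p = 0.0001 for each, the smallest possible), across genes, which are not independent replicates. Among the 331 highest-scoring peaks, 6 genes had at least 5.

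**Figure D1:**
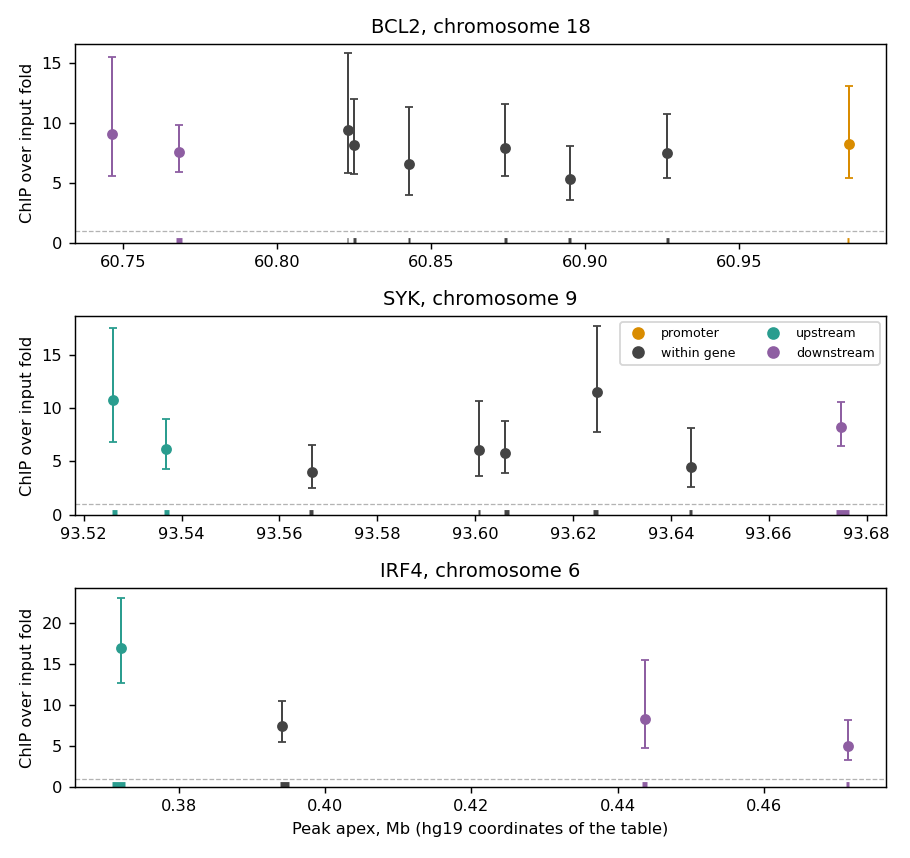
ChIP over input fold of each peak (vertical axis) against the position of its apex in Mb (horizontal axis, hg19) at BCL2, SYK and IRF4; points are peaks coloured by position class, bars are exact 95% intervals of counting error, marks on the axis are peak intervals and the dashed line is a fold of 1. The 9 peaks of BCL2 ran from 5.28 to 9.36-fold, the 8 of SYK from 3.98 to 11.6-fold and the 4 of IRF4 from 5.03 to 16.9-fold.

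Most peaks lay away from promoters. By the authors' classes, 344 peaks (52.0%, 48.2 to 55.9) lay within a gene, 155 (23.4%, 20.3 to 26.9) upstream and 162 (24.5%, 21.3 to 28.0) downstream. The promoter class, which reached 2000 bp from a TSS, held 36 peaks (5.45%, 3.84 to 7.46), among them those of CRYZ, IFITM1, ZNF580, BCL2, E2F1 and LMO2. A window of 5000 bp held 10.7% and a window of 1000 bp 3.21% of the 654 peaks with a TSS distance. Median distance to the TSS was 39.3 kb, with quartiles of 15.0 and 81.0 kb. Promoter peaks had a mean score of 2.74 ± 0.80 (SD, 36 peaks) and other peaks 2.61 ± 0.69 (625 peaks), a difference of 0.13 (−0.12 to 0.41) that did not pass a two-sided permutation test (p = 0.269). Wider peaks had higher scores across peaks (rho 0.64, r 0.49, permutation p = 0.0001 for each, the smallest possible), and rho was 0.30 among the 331 highest-scoring peaks. Peaks are not independent replicates.

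Of the 18 fixed lists, 4 held more named genes than expected with an adjusted p under 0.05 in the permutation test: plasma cell and ABC-type lymphoma genes, apoptosis genes, B lineage transcription factors and cell cycle genes. The list of plasma cell and ABC-type lymphoma genes had 6 of 28 members named, all marked Up, 14.5 times the length-matched expectation of 0.414 (permutation p = 0.0002, adjusted p = 0.0018). They were IRF4, the plasma cell and ABC transcription factor, with 16.9-fold (12.6 to 23.04) upstream of the gene, PIM1, a kinase gene, with 11.9-fold (7.45 to 19.9), SPIB, an Ets factor gene, with 11.6-fold (8.87 to 15.3), BCL2, TCF4 and FOXP1. The B lineage transcription factors had 4 of 24 members, IRF4, SPIB, BCL11A with 12.9-fold (5.58 to 36.5) and RUNX1 with 9.10-fold (5.601 to 15.6), which was 9.10 times the expectation (permutation test, adjusted p = 0.0096). The lists share IRF4 and SPIB. TCF4 is the induced factor itself. Without genes on chromosomes 3 and 18, where BCL2, TCF4 and FOXP1 lie, the plasma cell and ABC-type list had 3 of 24 members named. It still passed (permutation test, adjusted p = 0.0192). The table was chosen through a signature, so these excesses describe signature genes with a peak and are not independent evidence of binding preference. Restricting to peaks within 2000 bp of a TSS, where few genes keep a peak and no list has more than 1 member named, left no list past the threshold of 0.05.

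Apoptosis genes had 4 of 24 members named, all marked Up, 11.95 times the expectation (permutation p = 0.0002, adjusted p = 0.0018). BCL2L11, which encodes the pro-apoptotic protein BIM, had a peak of 14.3-fold (10.3 to 20.4) downstream. PMAIP1, which encodes NOXA, had 8 peaks with up to 11.2-fold (6.66 to 20.2). None lay within the gene: 6 were upstream and 2 downstream, the nearest 26821 bp from the TSS. BIK had 1 peak of 10.1-fold (6.01 to 18.3). The fourth member, BCL2, opposes the other 3 in function. Without genes on chromosomes 3 and 18, where BCL2 and PMAIP1 lie, the list was at 9.32 times the expectation and no longer passed (permutation test, adjusted p = 0.172).

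Cell cycle and MYC-family genes had 3 of 24 members named, 9.78 times the expectation (permutation p = 0.007, adjusted p = 0.0315). E2F1 had a promoter peak of 9.09-fold (6.36 to 13.4). The single MYC peak, at chromosome 8 from 128637428 to 128637612, had a fold of 3.67 (1.99 to 7.12), was 184 bp wide and was annotated with a transcript of the neighbouring gene CASC11. The third member was E2F2, whose interval included 1. The list did not pass when restricted to the 331 highest-scoring peaks (permutation test, adjusted p = 0.805), to peaks in or within 10000 bp of the gene (0.189) or to peaks within 50000 bp of the TSS (0.253).

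B cell receptor signalling genes had 3 of 30 members named, 5.91 times the expectation (permutation p = 0.0258), which missed the threshold after adjustment (adjusted p = 0.0929). It passed among the 331 highest-scoring peaks (permutation test, adjusted p = 0.0405) and in an unmatched Fisher's exact test (adjusted p = 0.0269). It did not pass in the other 5 settings, with permutation-test adjusted p-values of 0.0576 for Up genes alone, 0.0855 for peaks in or within 10000 bp of the gene, 0.221 without chromosomes 3 and 18, 0.336 within 50000 bp of the TSS and 1 within 2000 bp. NFATC1, a calcium-responsive factor gene, had 5 peaks with up to 18.4-fold (12.6 to 28.1). SYK, a proximal receptor kinase gene, had 8 with up to 11.6-fold (7.80 to 17.7).

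In the immunoglobulin list 1 of 16 members was named (permutation test, adjusted p = 0.381), IGHM, the constant region gene of IgM. The peaks named IGHM on chromosome 14 had folds of 19.2 (11.6 to 34.2) from 106131626 to 106133251 and 18.1 (10.1 to 35.8) from 106152851 to 106153901. A further 5 peaks named IGH@, chosen after their values were seen, had folds of 6.55 to 10.5. These 7 peaks spanned 241 kb, had no TSS distance and implied a shared gene end within 466 bp. The peaks named IGHM lay between those named IGH@, so the names do not tie a peak to the IGHM gene. Plasmacytoid dendritic cell genes had 2 of 26 members, SPIB and BCL11A (permutation test, adjusted p = 0.345), and E proteins with their inhibitors had 1 of 14, TCF4 (adjusted p = 0.731).

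Germinal centre B cell genes had 1 of 23 members, LMO2, with a promoter peak of 9.28-fold (5.04 to 18.7), and NF-kB genes had 1 of 30, TNIP2, with 8.08-fold (4.88 to 14.1). Both genes were marked Down, and neither list passed (permutation test, adjusted p = 0.994 for each). Ribosomal protein genes had 1 of 28, RPL5, with 4.53-fold (2.40 to 9.16, permutation test, adjusted p = 0.742). No member was named among antigen presentation, BET bromodomain and Mediator, T cell, myeloid, hepatocyte, skeletal muscle or neuronal genes, where 0.207 to 0.290 members were expected, so a count of 0 is not below chance.

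**Figure D2:**
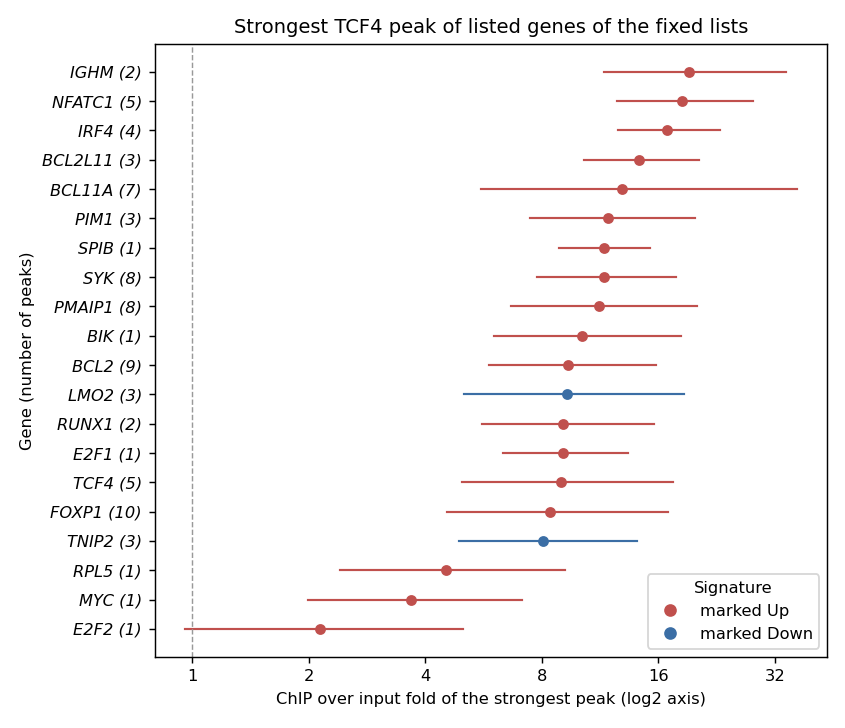
ChIP over input fold of the strongest peak (log2 axis) of fixed-list genes named by the table, with exact 95% intervals of counting error and the number of peaks in brackets; colour gives the direction in the signature. E2F2 at 2.14-fold has the only interval that includes 1, and a peak named IGHM, at 19.2-fold, is the highest.

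No difference between genes marked Up and Down passed its test in any of 6 measures of their peaks and length. Up genes such as IRF4 and SYK and Down genes such as LMO2, FAM49A and IFITM1 had 2.38 ± 1.80 (SD, 229 genes) and 2.52 ± 1.47 (46 genes) peaks per gene, a difference of −0.14 (−0.64 to 0.32, permutation p = 0.647). The strongest peak had a mean score of 2.94 ± 0.74 at Up genes and 2.98 ± 0.60 at Down genes, a difference of −0.04 (−0.24 to 0.14, permutation p = 0.702). Promoter peaks were 6.84% and 7.52% of a gene's peaks on average (permutation p = 0.846), and peaks within the gene 52.1% and 49.2% (permutation p = 0.67). Log10 distance of the nearest peak to the TSS averaged 4.08 and 4.04 (permutation p = 0.697), and log10 gene length 4.62 and 4.56 (permutation p = 0.462). Adjusted p-values were 0.842 to 0.846, and genes, not samples, were the units. Only signature genes with a peak are listed, so how often Up and Down genes are bound at all could not be compared.

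**Figure D3:**
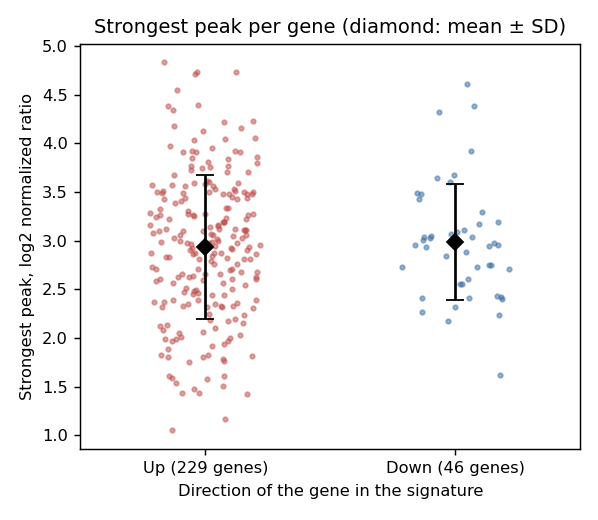
Score of the strongest peak per gene (the authors' normalized log2 ratio, vertical axis) for 229 Up genes and 46 Down genes; points are genes and diamonds with bars are means ± SD. The means of 2.94 and 2.98 differ by -0.04, with a 95% interval of -0.24 to 0.14.

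Chromosomes 3 and 18 held more of the table than their share of genes. Chromosome 3, with FOXP1, TRAK1 and SHQ1, had 128 peaks (19.4% against 5.34% of protein-coding genes, 3.63 times, exact binomial test, adjusted p = 1.78e-35). Chromosome 18, with TCF4, BCL2, NEDD4L, NFATC1, PMAIP1 and MBP, had 103 peaks (15.6% against 1.35%, 11.5 times, exact binomial test, adjusted p = 2.63e-72). Peaks of a gene are not independent, so genes were counted too: chromosome 3 had 60 genes (4.09 times, exact binomial test, adjusted p = 1.23e-19) and chromosome 18 had 37 (9.95 times, adjusted p = 7.11e-24). Counted by peaks, 6 chromosomes lay above and 12 below expectation past the threshold, and by genes 2 above and 4 below (chromosomes 4, 11, 17 and X). Shares add up to a whole, so the excess on chromosomes 3 and 18 lowers the others. The deficits were not tested apart from it. Chromosome 3 held 59 of 229 Up genes (25.8%) and 1 of 46 Down genes (2.17%, Fisher's exact p = 0.000121). Chromosome 18 held 37 Up genes (16.2%) and 0 Down genes (Fisher's exact p = 0.00137).

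**Figure D4:**
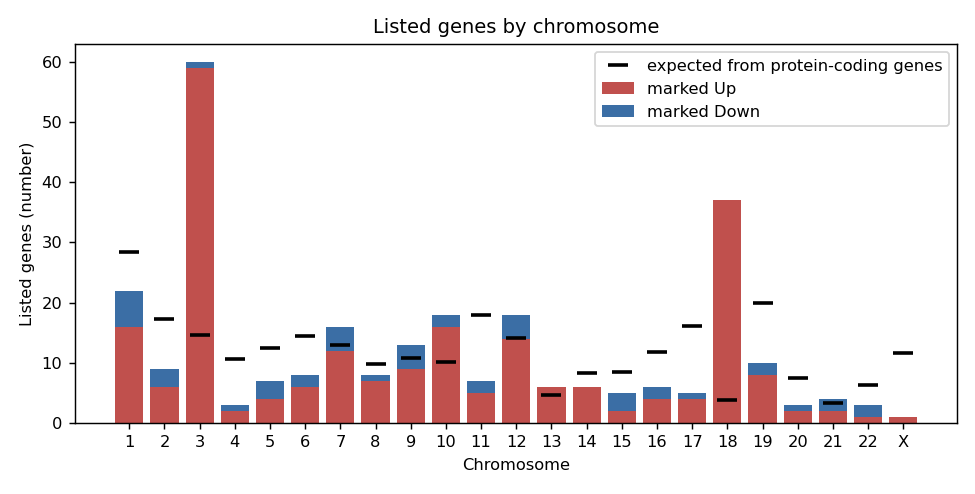
Number of listed genes per chromosome (bars, coloured by direction in the signature) with the number expected from protein-coding genes (black marks). Chromosome 3 with 60 genes and chromosome 18 with 37 stand above expectation, nearly all of them marked Up.

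Narrow peaks had more input signal per length. The 23 peaks of 200 bp or less, among them those of MYC and E2F2, 1 of BCL2 and 1 of MBP, had a median input density of 1.29 and a median fold of 3.20. The 75 peaks above 1000 bp had 0.495 and 8.13. Input density fell gradually with width, not in 1 step at 200 bp. Its median was 0.889 in peaks above 200 and up to 300 bp, 0.646 up to 400 bp and 0.529 up to 500 bp. ZNF580, with a 212 bp peak, had the highest ChIP density, 34.8, and an input density of 1.57.

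**Figure D5:**
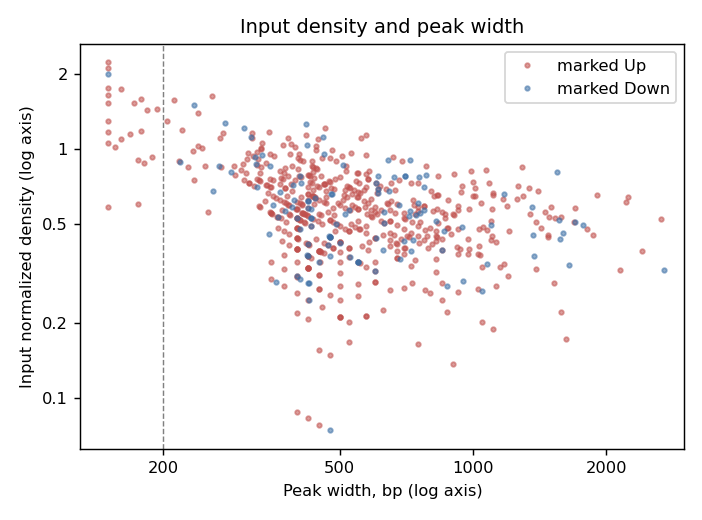
Normalized input density (log axis) against peak width in bp (log axis), with points as peaks coloured by direction in the signature and a dashed line at 200 bp. Median input density was 1.29 in the 23 peaks up to that width and 0.495 in the 75 peaks above 1000 bp.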

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

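Leaving out chromosomes 3 and 18, counting genes per chromosome and the Up against Down settings were chosen after the data were seen. Stricter score limits left 331 and 166 peaks by construction, with 117 genes at the latter and 6 genes with at least 5 peaks at the former (31 in full). The promoter share was 3.21% in a 1000 bp window and 10.7% in a 5000 bp window. Counting genes, 6 chromosomes passed in place of 18. Of 18 lists, 4 passed in the main comparison, 3 to 5 in other settings and 0 with peaks within 2000 bp of the TSS, where few genes keep a peak. There plasma cell and ABC-type genes were at 20.1 times, apoptosis genes at 21.5 times and cell cycle genes at 25.7 times the expectation (permutation test, adjusted p = 0.434 for each), and B lineage factors at 0 (adjusted p = 1). Cell cycle genes lost the call among the 331 peaks (4.64 times), near the gene body (7.88) and within 50000 bp of the TSS (7.67), and apoptosis genes without chromosomes 3 and 18 (9.32). The cause was not tested. Up minus Down, never past the threshold, changed sign for peaks per gene among the 331 peaks (0.19) and without chromosomes 3 and 18 for the strongest peak (0.0696), promoter share (1.01), log10 TSS distance (-0.0308) and log10 gene length (-0.0231). E-box content, random placement and chromosome length were not run. No paired analysis was possible because the series has 1 ChIP and 1 input library. Depth limits peaks with few input reads, such as SHQ1 with 2 (10.2 to 326-fold), and 565 of the 661 folds had an interval above 2.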

Other observations

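Every test below was chosen after the result was seen, except the input density at B cell genes. The pooled set of B cell genes was put together after gene names were seen, from lists fixed before the data were examined.

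The genes in this paragraph lie outside the fixed lists and were chosen after their values were seen, so they describe single genes and no group. BLK, a B lymphoid Src-family kinase gene marked Up, had 2 peaks with up to 12.1-fold (7.46 to 21). MDM4, a p53 inhibitor gene, had 4 with up to 11.5-fold (6.86 to 20.7), and SMAD2, on chromosome 18, 6 with up to 6.98-fold (4.61 to 10.96). RFC3, a replication factor gene, had 5 with up to 8.15-fold (4.93 to 14.2). Among Down genes, ITGAX, the integrin gene of CD11c, had 3 with up to 20.6-fold (14.4 to 30.4), PRNP 3 with up to 11.9-fold (7.07 to 21.3), and APOBEC3G, a cytidine deaminase gene, 2 with up to 7.89-fold (5.74 to 11.1). CR1, a complement receptor gene, had 1 of 5.55-fold (3.24 to 10.0).

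Chromosomes 3 and 18 held 96 of 229 Up genes (41.9%) and 1 of 46 Down genes (Fisher's exact p = 1.14e-08). This argues against denser binding or more copies there in TMD8 as the whole cause, if these act on genes of either direction alike. Input density in peaks wider than 200 bp was 0.875 (0.782 to 0.992) times that of other chromosomes on chromosome 3 and 1.096 (1.02 to 1.22) times on chromosome 18. The latter interval lies above 1, so slightly more copies there are not excluded. The excess of genes was 4.09 and 9.95 times. How copies change the number of genes called is not known, so the input ratios cannot be set against it. Up genes on chromosome 3 had 2.15 peaks per gene against 2.37 elsewhere, a difference of −0.216 (−0.716 to 0.326), as an excess of signature genes without more peaks per gene would give, while on chromosome 18 the 2.78 peaks per gene and the difference of 0.415 (−0.356 to 1.28) leave this open. Why the signature's Up genes lie on these chromosomes stays open, since its derivation is not given in the sources used here.

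Narrow peaks had 75.6 input reads per kb in 23 peaks against 31.1 in 638 wider ones, a ratio of 2.43 (2.15 to 2.73). This is beyond the counting noise of independent reads, but the interval leaves out the spread between peaks. The apex of narrow peaks lay within 5 bp of the border in 4 of 23 against 1 of 638 wider ones (Fisher's exact p = 5.49e-06). A zone of fixed length covers more of a narrow peak, so this count decides nothing. A candidate explanation, which no value here supports or excludes, is local background shared by both libraries, such as repeated sequence, since the sequence was not searched. No biological explanation was tested. The densest narrow peaks, at BLVRA, BCL2 and SLA, were each 150 bp wide with input densities of 1.99, 2.22 and 2.10 (chosen after their values were seen).

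The pooled B cell lists held 14 genes of the table, which included BCL11A, BCL2, FOXP1, IGHM, IRF4, LMO2, NFATC1, PIM1, RUNX1, SPIB, SYK, TCF4 and TNIP2. These 14 had 4.71 ± 2.79 (SD) peaks per gene and the other 261 had 2.28 ± 1.59. The other genes included BLK and IGH@, which are on none of the lists. Within length tertiles the difference was 2.27 (permutation p = 0.0001, the smallest possible), and 1.90 to 2.52 leaving out each gene. Lengths still vary within a tertile, and after a quadratic fit on log10 gene length the difference was 2.01 for all peaks (permutation p = 6e-05) and 1.28 for peaks inside the gene (permutation p = 0.00019). Wide empty surroundings that catch distant peaks are argued against in part by peaks inside the gene, 2.93 ± 2.46 against 1.16 ± 1.248, a difference of 1.56 (permutation p = 0.0006), although without chromosomes 3 and 18 it was 0.646 in 10 genes and missed the threshold (permutation p = 0.0675), while all peaks kept 1.36 (permutation p = 0.0035). Input density in peaks wider than 200 bp was 1.04 (0.953 to 1.12) times that of other genes, which argues against background or copy number in those peaks and leaves out the narrow ones, 1 of BCL2 among them. A denser set of TCF4 sites at B cell genes is a hypothesis found and tested on the same data, and the authors' choice of signature peaks, which may also give it, stays open.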
